A study of Mus musculus with 8 samples.

How the data were processed

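RNA from epididymal white adipose tissue of mice fed a high-fat diet was sequenced in 8 libraries, 4 from wild-type mice (WT, replicates 1, 2, 3 and 5) and 4 from mice with the knock-in allele (S273A, replicates 2, 3, 4 and 6). The genotype came from the genotype field of the labels and the replicate number from each sample's title. Per the labels' protocols, 400 ng of total RNA was depleted of ribosomal RNA, converted to cDNA without marking the strand, tagmented with Nextera XT, amplified for 12 cycles and sequenced as paired reads of 36 bases. The libraries therefore hold no strand information, so reads from a gene and from an overlapping gene on the other strand cannot be told apart. Whole-tissue RNA was used, so each value is a mixture over adipocytes, immune cells, vessels and other cells of the depot.

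The authors deposited 1 table of whole-number read counts per gene, with the libraries in 8 columns and a further column of feature lengths. Per the submitters' processing notes, which name tools without their roles, bcl2fastq 2.20.0, HISAT2 2.0.5, Picard 2.9.2, featureCounts 1.5.2 and edgeR 3.3.0 were used with the mouse build mm10. The annotation version, the treatment of duplicate reads and the counting of read pairs or of reads at several places are not given in the sources used here. The length column, per the file headers, gives the summed length of each row's features in bases, another quantity that entered no test. The deposited counts are not normalised: their sums ran from 14880239 to 18194889 per library. The table has 31854 rows, each a UCSC gene identifier joined to a symbol, and 9146 rows held no count in any library. A symbol stood on more than 1 row in 790 cases, covering 2891 rows; such rows were tested one by one, and the row with the highest total count stood for its symbol in a gene list. Short paired reads from near-identical genes can be split or dropped in ways that were not recorded, so values of multigene families are uncertain.

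Counts were analysed as deposited with edgeR 4.0.16 in R 4.3.3. Rows were kept by filterByExpr with its defaults, which left 15667 rows. With 4 libraries per genotype these ask for a count of about 10 in at least 4 libraries and a total of 15. The default share of 0.7 applies only to groups of more than 10 libraries. Library sizes were scaled by TMM. Dispersions were estimated with estimateDisp, and genotype was tested with glmQLFit, with the robust option, and glmQLFTest; the quasi-likelihood method was the installed version's default. P-values were adjusted by the Benjamini-Hochberg method over all tested rows, and a gene was called at an adjusted p under 0.05. Standard errors of log2 fold changes were taken from the F statistic, with 95% confidence intervals from its degrees of freedom. Levels are normalised CPM, read counts scaled by the TMM-corrected library size, given as mean ± SD over 4 libraries. The model had no covariate, because the labels state no litter, batch or pairing; only 2 replicate numbers occur in both genotypes, and these were not treated as pairs.

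Named genes followed a rule set before the data were examined: Pparg, Gdf3 and Cdk5 always; genes past the threshold, with a mean log2 CPM of at least 1 and no overlap between the genotypes; and, if fewer than 10 genes passed, the 10 genes with the smallest unadjusted p in each direction that met the other conditions and had a proper symbol, stated not to have passed. For each described list, up to 4 members with the smallest p were named, and any of the 17 earlier Ser273 genes. Some items that the rule takes are not reported here. A total of 34 gene lists was set at the same time, from general knowledge of adipose biology and of the cell types in the depot. Of their 623 entries, 585 matched a row by exact symbol. The 32 lists with at least 5 tested members were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, and again with the correlation estimated from the data and with fry. The list of 15 mitochondrially encoded genes had 0 matching rows, and the list of epididymis and testis markers had 1 tested member of 18 (14 had a row), so neither was tested. A list score is the mean over members of log2 CPM, with a prior count of 2, minus each gene's mean over the 8 libraries.

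Gene positions were taken by symbol from GENCODE release M21 on GRCm38, the assembly that mm10 names. A single position was found for 13743 of the 15667 tested rows. Of the 21 genes reported under the rule, 17 shared no exon bases with another annotated gene. The other 4 were Adap2, Cyp24a1, Gpr155 and Kifc3, each overlapping a gene on the opposite strand; their values are uncertain to that extent.

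The test was checked on counts simulated from the real means, dispersions and library sizes for 15556 tested genes, with 200 genes changed. At simulated folds of 1.25, 1.5, 2 and 4 it recovered 4, 35, 46 and 49 of 50 changed genes, and 9 of its 143 calls were false. DESeq2 made 172 calls on the same counts, of which 25 were false. For simulated lists, both of the 2 lists shifted by 0.25 on the log2 scale were called, and 0 of the other lists. The simulated genes varied independently of one another, unlike members of real lists.

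Alternatives set before the data were examined were RLE size factors, DESeq2 1.42.0, limma-voom with sample weights, the earlier quasi-likelihood method, no filter, a filter of CPM of at least 1 in at least 4 libraries, leaving out the 10 most abundant rows (no row matched the mitochondrial genes that were to be left out with them), 1 surrogate variable (sva 3.50.0), the replicate number as a block, an adjusted p threshold of 0.1 and leaving out each library in turn. Added after seeing the data were the newer quasi-likelihood method, the fit without the robust option and edgeR's exact test. Genotype labels were also reassigned in all 35 ways of splitting 8 libraries into 4 and 4. Exact permutation tests of single values were two-sided; with 4 against 4 the smallest p they can give is 0.0286. Principal components were computed on log2 CPM of the tested rows. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.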

Results

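Gene expression was measured in epididymal white adipose tissue, the fat depot beside the testis, of mice on a high-fat diet. The mice carried either wild-type PPAR-gamma or a knock-in allele in which serine 273 is replaced by alanine (S273A). PPAR-gamma, encoded by Pparg, is the nuclear receptor that drives fat cell formation and is the target of the thiazolidinedione drugs; the alanine cannot be phosphorylated by the kinases, Cdk5 among them, that act on this serine. There were 4 libraries per genotype. Total counts ran from 14880239 to 17266209 in WT and from 16161127 to 18194889 in S273A, and between 19469 and 19896 rows had at least 1 count in a library. Ribosomal precursor Rn45s took 1.62% ± 0.10 of the counts in WT and 1.61% ± 0.07 in S273A (SD, n = 4 each). Correlations of log2 CPM between pairs of libraries lay between 0.985 and 0.993, and every pair differed by more than sampling noise (chi-square per degree of freedom of 5.53 or more). The labels do not state that each library came from a separate animal, so p-values measure the spread between these libraries, which may be technical.

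The comparison asked which transcripts differ in this depot when Ser273 cannot be phosphorylated. Gdf3, a secreted member of the TGF-beta family that earlier work links to Ser273, had the smallest p of all rows and the largest fold among rows with a mean log2 CPM of at least 1. It was at 17.4 ± 1.12 CPM in WT and at 3.96 ± 2.35 CPM in S273A (SD, n = 4 each), 4.41-fold lower in the knock-in. The counts were 309, 314, 231 and 303 in WT and 44, 44, 129 and 57 in S273A, so all 4 S273A libraries lay below all 4 WT libraries. The log2 fold change was -2.14 (SE 0.30, 95% confidence interval -2.82 to -1.47). Gdf3 (row identifier uc009dpm.1) lies on the minus strand of chromosome 6, from 122605403 to 122610087 (GRCm38), in 2 exons, and no annotated gene overlaps it. Its unadjusted p was 4.12e-05 in edgeR's quasi-likelihood test over 15667 rows, and the adjusted p was 0.646, which did not pass. Because Gdf3 was named before the data were examined, the unadjusted p is the planned reading for it as a single gene. DESeq2 gave an adjusted p of 4.44e-08 and limma-voom one of 0.034 for Gdf3; the range over all alternatives was 4.44e-08 to 1. Without S273A replicate 4, the S273A library with the highest level (7.41 CPM), edgeR called it with an adjusted p of 0.000383 and a log2 fold change of -2.64. An exact permutation test of its log2 CPM gave p = 0.0286, the smallest that 4 against 4 can give, which follows from the lack of overlap.

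**Figure D1:**
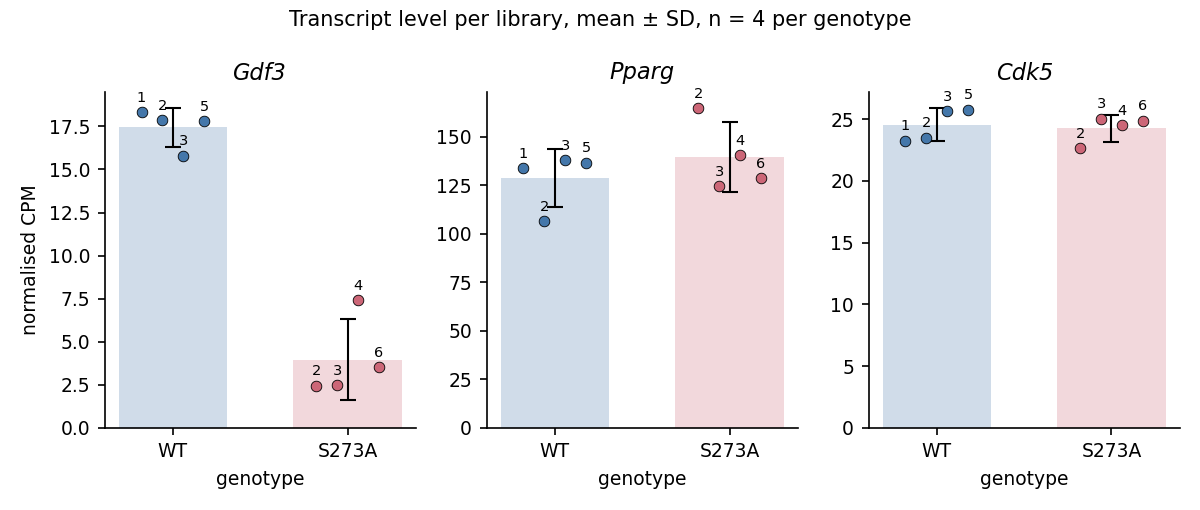
Normalised CPM (vertical axes, starting at 0) of Gdf3, Pparg and Cdk5 in each library, by genotype; points are libraries marked with their replicate number, bars are means and error bars are SD (n = 4). Gdf3 lies between 15.8 and 18.3 CPM in WT and between 2.45 and 7.41 CPM in S273A, whereas the genotypes overlap for Pparg and Cdk5.

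The Pparg transcript (row identifier uc009dis.3) was at 129 ± 15.0 CPM in WT and 140 ± 18.1 CPM in S273A (SD, n = 4 each), a log2 fold change of 0.12 (SE 0.11, 95% confidence interval -0.12 to 0.36; edgeR unadjusted p 0.299, adjusted p 1). No alternative called it, and its size turned on the method and on single libraries: 0.03 without S273A replicate 2, 0.04 without WT replicate 2, 0.18 without S273A replicate 3, 0.035 in limma-voom and 0.24 with a term for the replicate number. The allele changes 1 codon, so this level does not check the genotype labels. In the annotated transcript of 505 residues, codon 273 encodes serine and lies in exon 5 of 7, at 115463283 to 115463285 of chromosome 6. The gene spans 115360951 to 115490399 on the plus strand. Cdk5, one of the kinases for this serine, was at 24.5 ± 1.36 CPM in WT and 24.3 ± 1.10 CPM in S273A (log2 fold change -0.02, SE 0.07; 95% confidence interval -0.16 to 0.13).

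Gdf3 lies 7.12 Mb from Pparg on the same chromosome. Of the 16 tested genes centred within 0.5 Mb of Gdf3, itself included, the adjacent Apobec1, an RNA-editing cytidine deaminase, and Dppa3, a germ cell gene, had log2 fold changes of -0.09 (SE 0.10) and 0.53 (SE 0.27). The neighbour with the highest estimate was Rimklb (0.79, SE 0.36, unadjusted p 0.052), at 0.52 CPM in WT and 0.89 in S273A, and the lowest was the lectin gene Clec4a1 (-0.30, SE 0.13, unadjusted p 0.0418), at 42.7 and 34.7 CPM. Within 15 Mb of Pparg, the 188 genes other than Gdf3 with a mean log2 CPM of at least 1 had log2 fold changes between -0.36 and 0.64, and none of them was called. These neighbours were named after their values were seen.

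**Figure D2:**
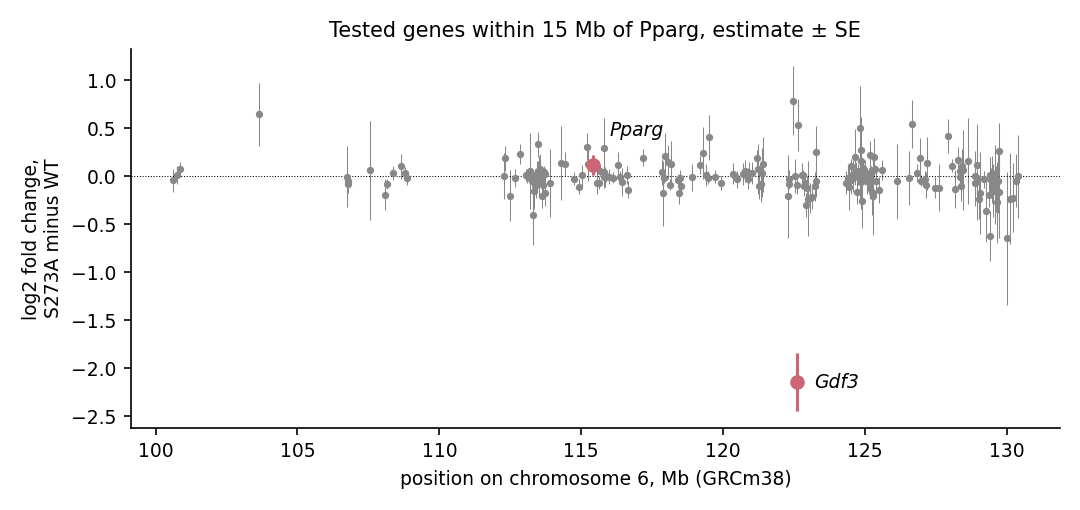
Log2 fold change (S273A minus WT, vertical axis) of tested genes against their position on chromosome 6 in Mb (GRCm38, horizontal axis), within 15 Mb of Pparg; points are estimates and lines are SE. Gdf3, at -2.14, lies apart from the other genes of the region, and Pparg is at 0.12.

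Across the transcriptome, 0 of 15667 rows passed an adjusted p under 0.05 in edgeR, 0 higher and 0 lower in S273A. DESeq2 and limma-voom each called 1 gene, Gdf3. At an unadjusted p under 0.05 there were 229 rows in edgeR (143 higher, 86 lower) and 315 in limma-voom, against 783 expected by chance in edgeR. DESeq2, run on 22694 rows without the filter, gave 216, so its count has another chance level. The genotypes did not overlap in 186 rows, 1.19% of those tested, where chance gives 2.86%. The 95% confidence interval of a log2 fold change reached, in the median, 0.21 to either side for the 13807 rows with a mean log2 CPM of at least 1, and only 5 of these rows had an estimate beyond 1 in either direction. Counts were simulated at this depth and spread with 200 genes changed at once. Of genes changed 2-fold, 46 of 50 were called, and of those changed 1.25-fold, 4 of 50. Differences well under 1.5-fold were therefore mostly not detectable for single genes. The simulated genes varied independently of one another, and the real fit gave fewer low p-values than chance, so these recovery rates may not carry over. The adjustment is stricter where few genes change, so larger changes can be missed as well: Gdf3, 4.41-fold lower, was not called by edgeR.

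Apart from Gdf3, the genes with the smallest p that separated the genotypes did not pass (edgeR adjusted p of 1 for each), and their estimates were small. Lower in all 4 S273A libraries were Gpr155, a lysosomal cholesterol sensor, at 64.3 ± 5.04 CPM in WT against 50.8 ± 3.89 in S273A (log2 fold change -0.34), and Cyp24a1, the enzyme that inactivates vitamin D, at 2.52 ± 0.17 against 1.63 ± 0.30 (-0.62). Nsun3, a methyltransferase of mitochondrial tRNA, was at 9.79 ± 0.39 against 7.79 ± 0.42 CPM (-0.33), and Ulbp1, a ligand of an activating receptor on NK cells, at 15.2 ± 0.74 against 12.4 ± 1.25 CPM (-0.29). The GTPase gene Gem (-0.41), the receptor gene Gpr85 (-0.48), Adap2 (-0.17) and Fam129a (-0.16) were also lower. Higher in all 4 were Nabp1, a single-stranded DNA binding protein, at 262 ± 21.0 CPM in WT against 368 ± 72.7 in S273A (0.49), and Ank3, a membrane anchor protein, at 1.5 ± 0.23 against 2.24 ± 0.23 CPM (0.57). Slc12a5, a potassium-chloride cotransporter, was at 3.25 ± 0.16 against 4.45 ± 0.31 CPM (0.45), and Kifc3, a kinesin, at 38.6 ± 0.53 against 45.0 ± 2.28 CPM (0.22). The others were Isg20, an exonuclease gene (0.30), Myo5b, a motor protein gene (0.28), Ccdc149 (0.26), the integrin gene Itga3 (0.24), Rps19 (0.18) and Yeats2 (0.15). Rps19 encodes a ribosomal protein with processed copies in the genome, so its count is uncertain.

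**Figure D3:**
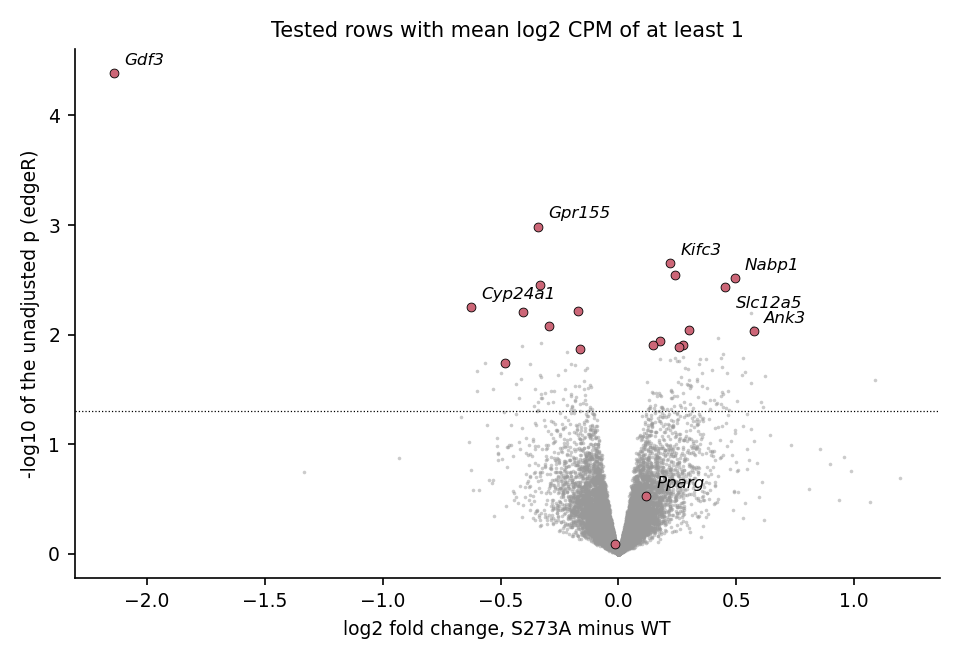
Unadjusted p of edgeR's quasi-likelihood test, as -log10 (vertical axis), against log2 fold change, S273A minus WT (horizontal axis), for the 13807 tested rows with a mean log2 CPM of at least 1; red points are the genes named here under the fixed rule and the dotted line marks a value of 0.05. Gdf3, at -2.14, stands apart; no row passed after adjustment in this test.

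Genes that earlier work on fat cells tied to phosphorylation of Ser273 were tested as a list of 17. Its members were recalled from general knowledge, not taken from a published source, and no direction was set for each. None was called over all genes, and 0 were called when adjusted over the list alone (smallest edgeR adjusted p 0.622). Estimates were positive for 12 and negative for 5, with a median log2 fold change of 0.04. The smallest p-values belonged to the clock repressors Nr1d2, at 76.0 ± 7.71 CPM in WT and 86.2 ± 4.41 in S273A (log2 fold change 0.18, SE 0.07), and Nr1d1, at 62.3 ± 12.7 and 75.9 ± 10.1 CPM (0.29, SE 0.15). The adipokine genes Adipoq (683 ± 110 and 704 ± 105 CPM) and Rarres2 (126 ± 9.77 and 125 ± 7.27 CPM) differed by less than the spread between replicates. Cfd, which encodes adipsin, was at 196 ± 10.2 CPM in WT and 252 ± 165 CPM in S273A, where S273A replicate 2 had 497 CPM and the other 3 libraries 135 to 188 CPM. The list did not pass camera (adjusted p 0.0582, higher), which turned on single libraries: it was called higher without WT replicate 1 (median 0.07, adjusted p 0.0254), WT replicate 3 (0.11, 0.00797), S273A replicate 3 (0.10, 0.00959) or S273A replicate 6 (0.10, 0.0223), while the median was 0.01 without WT replicate 2 (adjusted p 0.673), -0.01 without S273A replicate 2 (0.904) and 0.02 without S273A replicate 4 (0.116). The list did not pass camera with an estimated correlation (adjusted p 0.682) either. In the earlier work, as recalled, these genes went in both directions, so a test for change in either direction is the one that fits. By that test, fry's, the list did not pass (adjusted p 0.922).

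Mesothelial markers, genes of the cell layer covering the depot, were higher in S273A with camera's preset correlation: 14 of 14 members had positive estimates, with a median log2 fold change of 0.28 (adjusted p 4.04e-10, and 0.682 with an estimated correlation, where the call was lost). The extreme list scores were 0.41 in S273A replicate 4 and -0.46 in WT replicate 3; the median was 0.17 without the first (adjusted p 0.000506) and 0.19 without the second (adjusted p 0.000179). Examples are Slpi, a protease inhibitor, at 17.9 ± 4.05 CPM in WT and 24.3 ± 5.14 in S273A, Msln, mesothelin, at 18.7 ± 4.38 and 23.5 ± 2.30, and the uroplakin gene Upk3b at 47.6 ± 8.80 and 58.7 ± 9.97 (SD, n = 4 each). Red blood cell markers were higher as well, in 8 of 8 members (median 0.43, adjusted p 3.02e-05), a call also lost with an estimated correlation (adjusted p 0.682). The erythrocyte membrane genes Epb42 (0.50 ± 0.21 and 1.32 ± 0.86 CPM) and Slc4a1 (5.77 ± 2.39 and 10.9 ± 9.53 CPM) are examples, and the high values came from S273A replicates 4 and 6, with list scores of 0.62 and 1.06. Without S273A replicate 6 the red blood cell median was 0.15 and the call was lost (adjusted p 0.0864); without S273A replicate 4 it was 0.28 (adjusted p 0.0224). No member of either list was called, over all genes or adjusted over the list alone. The 2 list scores overlapped between genotypes, with an exact permutation p of 0.143 for mesothelial markers and 0.343 for red blood cell markers.

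Clock genes and nuclear genes of the respiratory chain were the other 2 lists higher in S273A with the preset correlation, and both calls were lost with an estimated one (adjusted p = 0.682 each). Clock genes had 15 of 17 positive estimates and a median of 0.08 (adjusted p 0.00423). Per2, a core repressor of the clock, was at 17.6 ± 2.59 CPM in WT and 21.3 ± 2.51 in S273A (log2 fold change 0.28). Nr1d1 and Nr1d2 belong both to the clock list and to the earlier Ser273 genes, so those lists are not separate observations. Respiratory chain genes had 24 of 27 positive estimates and a median of 0.06 (adjusted p 0.00101), among them Cyc1, cytochrome c1, at 54.2 ± 6.24 and 60.8 ± 5.88 CPM, and Atp5o, an ATP synthase subunit, at 48.1 ± 7.76 and 55.6 ± 6.20 CPM. Without WT replicate 2 the respiratory chain median was -0.003 (adjusted p 0.673), and without S273A replicate 4 it was 0.01 (adjusted p 0.658). The clock call was lost without WT replicate 2 (median 0.12, adjusted p 0.0795) and without S273A replicate 2 (median 0.02, adjusted p 0.251).

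Macrophage markers, cell cycle genes and interferon-stimulated genes were lower in S273A with the preset correlation, and none of the 3 calls held with an estimated one (adjusted p = 0.682 each). Of the macrophage markers, 16 of 18 had negative estimates, with a median of -0.11 (adjusted p 0.000464); Csf1r, the receptor for the macrophage growth factor, was at 763 ± 58.8 CPM in WT and 701 ± 49.2 in S273A, and Mrc1, a mannose receptor, at 668 ± 50.1 and 601 ± 86.0 CPM. Cell cycle genes had 20 of 24 negative estimates and a median of -0.10 (adjusted p 0.00284), with the kinase Cdk1 at 12.8 ± 1.35 and 11.4 ± 1.86 CPM and the replication helicase subunit Mcm3 at 39.2 ± 2.78 and 35.6 ± 3.75 CPM. Without S273A replicate 2, whose cell cycle score was -0.49, that median was 0.03 (adjusted p 0.267), and without WT replicate 3 it was -0.03 (adjusted p 0.399). Interferon-stimulated genes had 17 of 21 negative estimates and a median of -0.08 (adjusted p 0.0134), with the RNA sensor gene Ifih1 at 74.5 ± 6.96 and 68.2 ± 6.84 CPM. Their call was lost in 5 of the 8 fits without 1 library: WT replicate 1 (median -0.03, adjusted p 0.664), 2 (-0.10, 0.201) or 3 (-0.07, 0.1), or S273A replicate 2 (-0.04, 0.357) or 4 (-0.03, 0.342). The macrophage call was lost without WT replicate 2 (median -0.06, adjusted p 0.22) and without S273A replicate 4 (median -0.05, adjusted p 0.091), and the median was -0.05 without S273A replicate 2 (adjusted p 0.0169). No member of the 3 lists was called.

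**Figure D4:**
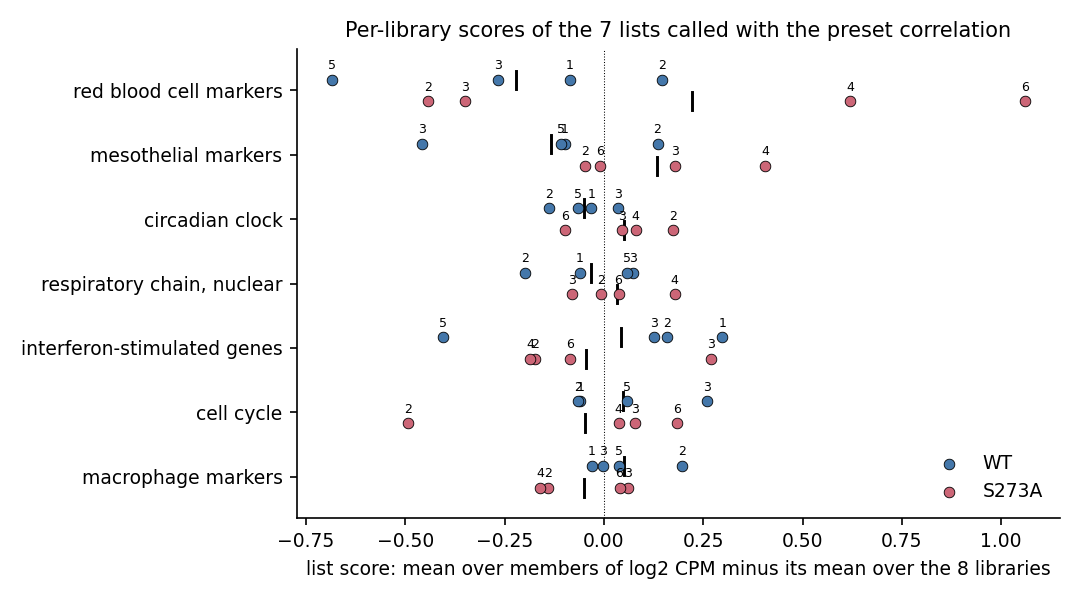
List scores per library (horizontal axis: mean over members of log2 CPM minus the gene's mean over the 8 libraries) for the 7 lists called with the preset correlation; points are libraries marked with their replicate number and black ticks are genotype means (n = 4). The genotypes overlap in each list; red blood cell scores run from -0.69 in WT replicate 5 to 1.06 in S273A replicate 6.

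The remaining function lists were not called with all 8 libraries. Of the 25 lists not called, 19 were called in at least 1 of the 8 fits without 1 library, so these results depend on single libraries as well. PPAR-gamma target genes, such as the lipase gene Pnpla2 (807 ± 83.5 CPM in WT, 889 ± 83.4 in S273A), had a median log2 fold change of 0.04 over 26 members (camera adjusted p 0.103). They were called lower without WT replicate 2 (median -0.05, adjusted p 0.0257) and higher without WT replicate 3 (0.11, 0.000282), WT replicate 5 (0.07, 0.0194), S273A replicate 3 (0.11, 0.000744) or S273A replicate 6 (0.05, 0.0441). De novo lipogenesis had a median of 0.06 over 17 members (adjusted p 0.0748), with its smallest p for Acacb, the acetyl-CoA carboxylase of mitochondria, at 170 ± 24.3 and 217 ± 38.2 CPM. Fatty acid oxidation (median 0.04, adjusted p 0.103) and insulin signalling (median 0.02, adjusted p 0.0841) did not pass, nor did thermogenic genes (median 0.07, adjusted p 0.297). Medians were 0.005 for the Ser273 kinases and corepressors (adjusted p 0.6), 0.02 for the extracellular matrix (0.821), 0.03 for the unfolded protein response (0.21), 0.02 for the hypoxia response (0.703) and -0.05 for inflammatory cytokines (0.186). Adipokines (median 0.03, mean -0.07, camera adjusted p 0.358, lower) and the BMP and Smad pathway (median 0.01, mean -0.08, adjusted p 0.21, lower) both contain Gdf3, and their tests and medians differ in sign. Gdf3 was the 1 member of each called when adjusted over the list alone (edgeR adjusted p 0.00066 and 0.00103). The BMP and Smad list was the only 1 of 32 to pass fry's test for change in either direction (adjusted p 0.0138), and Gdf3 alone carried it: without Gdf3, a fit chosen after seeing the data, the adjusted p was 0.953. Handling stress genes, such as Fos at 63.8 ± 9.83 and 55.4 ± 7.86 CPM, had a median of -0.04 (adjusted p 0.297).

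Markers of the other cell types did not pass with all 8 libraries either, and some medians turned on single libraries. That of B and plasma cell markers ran from -0.08 without S273A replicate 3 (camera adjusted p 0.102) to 0.405 without WT replicate 2 (0.00109). That of T and NK cell markers ran from -0.314 without WT replicate 5 (5.14e-08) to 0.02 without S273A replicate 4 (0.916). Adipocyte markers had a median log2 fold change of 0.07 (15 of 18 positive, camera adjusted p 0.105) and lipid-associated macrophage markers one of -0.03 (12 of 17 negative, adjusted p 0.22), with Mmp12, a macrophage elastase, at 356 ± 108 CPM in WT and 302 ± 106 in S273A. The median was -0.14 for antigen presentation and dendritic cell markers (adjusted p 0.0582), -0.10 for T and NK cell markers (0.108), 0.19 for B and plasma cell markers (0.151) and 0.03 for neutrophil and mast cell markers, whose test pointed lower (0.608). It was 0.08 for endothelial and lymphatic markers (0.0582), 0.10 for mural and smooth muscle cells (0.0582), -0.02 for fibroblasts and preadipocytes (0.714), 0.18 for the 5 tested skeletal muscle markers (0.0849) and 0.007 for nerve and Schwann cells (0.6). Among epididymis and testis markers, Cldn10 was the only tested member, at 2.59 ± 0.93 and 2.72 ± 0.53 CPM.

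Libraries did not group by genotype. The first 4 principal components took 29.2%, 20.1%, 13.2% and 11.6% of the variance. No difference between the genotypes was detected on any of them (exact permutation p of 0.771, 1, 0.6 and 0.543). WT replicate 2 (-27.8) and S273A replicate 3 (-20.8) lay at one end of the first component, and S273A replicate 2 (-31.8) lay apart from the other libraries on the second.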

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

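The values below were picked out because 1 of the 4 libraries of a genotype stood far from the other 3, by Dixon's ratio of its gap to the nearest library over the whole range. Of 286 groups of 4 libraries tested, 18 passed the 95% limit where chance gives about 14.3, or 1 in 20, so single entries carry little weight. No biological or technical explanation was tested for them.

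S273A replicate 2 accounted for 6 of the 18. Its Cfd level, adipsin, was 497 CPM against 135 to 188 CPM in the other S273A libraries (ratio 0.852), and its Cyp2f2 level was 2.56 against 0.23 to 0.55 CPM (ratio 0.861). Txnip, which encodes a thioredoxin-binding protein, was at 1361 against 1179 to 1201 CPM (ratio 0.88), the insulin receptor adaptor Grb10 at 114 against 90.3 to 92.4 CPM (ratio 0.914) and the cadherin gene Cdh19 at 1.67 against 0.67 to 0.75 CPM (ratio 0.928). The interferon-stimulated gene Rtp4 was lower there, at 11.4 against 14.6 to 15.1 CPM (ratio 0.855).

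Of the other S273A libraries, replicate 4 had Cox7c, a respiratory chain subunit, at 7.98 against 5.96 to 6.28 CPM (ratio 0.846) and the small heat shock gene Hspb1 at 24.3 against 18.01 to 18.95 CPM (ratio 0.85). The neutrophil collagenase gene Mmp8 was at 3.38 CPM in replicate 6 against 0.40 to 0.89 CPM (ratio 0.836).

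In WT, replicate 2 had Pparg at 106 CPM against 134 to 138 CPM (ratio 0.866), Cdk1 at 10.8 against 13.3 to 13.8 CPM (ratio 0.844) and a thermogenic list score of -0.52 against 0.05 to 0.14 (ratio 0.851). Replicate 5 had the interferon-stimulated gene Bst2 at 24.9 against 33.5 to 34.9 CPM (ratio 0.851), Mmp14 at 201 against 177 to 181 CPM (ratio 0.846) and an antigen presentation score of -0.32 against 0.12 to 0.19 (ratio 0.868). Replicate 1 had Apln, which encodes apelin, at 16.9 against 10.1 to 10.6 CPM (ratio 0.923). Replicate 3 had Vegfa at 102 against 114 to 116 CPM (ratio 0.86), and Rn45s took 1.78% of its counts against 1.56 to 1.59% (ratio 0.848).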

How the results depend on the processing

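The newer quasi-likelihood method, the fit without the robust option, edgeR's exact test and the list test without Gdf3 were chosen after seeing the data; the other alternatives were set before. The edgeR count of 0 called genes became 1, lower in S273A, in DESeq2, in limma-voom and in the exact test, and it ranged from 0 to 1 over the fits without 1 library; in each of these the gene was Gdf3. Gdf3 kept its direction in all 21 alternatives. Its log2 fold change was -2.14 in DESeq2 (adjusted p 4.44e-08), -2.26 in limma-voom (adjusted p 0.034) and -2.14 in the exact test (adjusted p 3.51e-07), and between -2.64 and -1.96 without 1 library, where only the fit without S273A replicate 4 called it (adjusted p 0.000383). It was not called with RLE size factors (0.656), no filter (0.999), the stricter filter (0.673), the 10 most abundant rows left out (0.688), 1 surrogate variable (0.999), the newer method (0.389) or the fit without the robust option (0.528). The earlier quasi-likelihood method is the installed default and gave the reported values again. No row lay under an adjusted p of 0.1 in the main edgeR fit with all libraries. The other named genes gave 399 values under the alternatives, 396 in the reported direction and 0 past the threshold. The other 3 are Cdk5, at -0.017 with all libraries, without WT replicate 3 (0.008), WT replicate 5 (0.007) or S273A replicate 2 (0.015). Apart from Cdk5, these genes were chosen because the genotypes did not overlap, which largely fixed their direction. The threshold of 0.1 and the earlier method also reuse the main fit. The shared direction is therefore no sign of stability. The Pparg estimate, 0.118, ran from 0.028 to 0.177 without 1 library, and the count of earlier Ser273 genes adjusted over the list alone stayed at 0 in each fit run for it.

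The counts of lists, 4 higher and 3 lower, depend on the correlation and on single libraries. With an estimated correlation and with fry they were 0 and 0. Without 1 library they ran from 3 to 13 higher and from 1 to 6 lower. Medians do not depend on the test, so all 7 calls were lost with an estimated correlation (adjusted p 0.682 each) and with fry (adjusted p 0.82 each) at unmoved medians: mesothelial 0.283, red blood cell 0.427, clock 0.0752, respiratory chain 0.0578, macrophage -0.105, cell cycle -0.0975 and interferon -0.0848. The mesothelial call was kept in 8 of 8 fits without 1 library and the red blood cell call in 7 of 8. Medians without 1 library ran from 0.173 to 0.385 for mesothelial, 0.154 to 0.594 for red blood cell, 0.0201 to 0.128 for clock, -0.0033 to 0.0958 for respiratory chain, -0.148 to -0.0513 for macrophage, -0.182 to 0.0279 for cell cycle and -0.193 to -0.0265 for interferon genes. The respiratory chain median reversed to -0.0033 without WT replicate 2, and the cell cycle median to 0.0279 without S273A replicate 2. With 1 surrogate variable the interferon median was -0.042 (adjusted p 0.117) and the call was lost, and the respiratory chain median was 0.0344 (adjusted p 0.016). In fry's test for change in either direction, the BMP and Smad list passed with Gdf3 (adjusted p 0.0138) and not without it (0.953). The causes of the other changes were not tested.

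Only replicate numbers 2 and 3 occur in both genotypes, and same-numbered libraries did not deviate together (r of -0.08 and -0.21, against up to 0.47 for WT replicate 2 with S273A replicate 3), so the numbers do not pair the samples. With the replicate block, in which only those 4 libraries inform the genotype term, 0 genes were called, Gdf3 was at -2.77 (adjusted p 1), and 7 lists were called higher and 7 lower. The red blood cell median was then -0.228 and called lower (adjusted p 4.66e-06), and the respiratory chain median was 0.0291 (adjusted p 0.778). The other 5 calls were kept, with larger medians for cell cycle (-0.317, adjusted p 1.25e-14) and clock genes (0.143, adjusted p 0.00509) and smaller ones for mesothelial (0.224), macrophage (-0.0952) and interferon genes (-0.0778).

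Depth and spread limit small changes. The 95% intervals reached 0.21 to either side in the median row with a mean log2 CPM of at least 1. Of 50 simulated changes of 1.25-fold, 4 were recovered, so single-gene changes of that size stay mostly out of reach. The simulation changed 200 genes at once, so with few changed genes larger changes can be missed as well.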

Other observations

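All tests of the separate lists over the 35 splits were chosen after the lists' calls were seen; the other tests here were set beforehand. Of the 10806 rows with a mean log2 CPM of at least 3, the median SD over the 8 libraries was 0.11. Gdf3 had the largest SD among them, 1.30, with its own mean log2 CPM at that limit. Of the 40 rows with the largest SD, Jchain, the joining chain of secreted antibodies, ran from 79.2 CPM in WT replicate 5 to 305 in WT replicate 2; Cd8a, of cytotoxic T cells, from 3.22 in S273A replicate 4 to 13.6 in WT replicate 1; and Cxcl9, a T cell attractant, from 18.025 in WT replicate 5 to 69.9 in WT replicate 1. T and NK cell scores were 0.40, 0.46 and 0.04 in WT replicates 1, 2 and 3 and -0.67 in WT replicate 5, and 0.02, 0.43, -0.48 and -0.20 in S273A replicates 2, 3, 4 and 6. These genes were named after their values were seen.

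S273A replicate 2 stood apart in other genes. Cyp2e1, a cytochrome P450, was at 352 CPM there against 48.5 to 76.0 CPM in the other 7 libraries, and B3gnt7, a glycosyltransferase, at 87.9 against 11.0 to 38.8 CPM. The same library had the highest adipocyte score (0.35), the lowest cell cycle score (-0.49) and the lowest B and plasma cell score (-0.59). In WT replicate 3, Eps8l1, an actin regulator, was at 1.44 CPM against 5.92 to 20.8 CPM elsewhere. Lars2, the leucyl-tRNA synthetase of mitochondria, was at 147 CPM in S273A replicate 4 against 38.5 to 77.9 CPM elsewhere.

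For the lower Gdf3 transcript, a loss across macrophages in the S273A tissue is argued against by the marker medians. These were -0.105 for macrophages and -0.025 for lipid-associated macrophages, far from Gdf3's -2.14. The medians do not cover a smaller set of cells that may express Gdf3, so cell make-up stays open to that extent. Reads shared with an overlapping gene are argued against as well, since 0 annotated genes overlap Gdf3. Over all rows, chance stays open in edgeR's quasi-likelihood test (adjusted p 0.646), although DESeq2 and limma-voom called Gdf3. Read as a single gene named beforehand, Gdf3 had an unadjusted p of 4.12e-05 in edgeR's test. That reading argues against chance, within the limit of 4 libraries per genotype. Also open is a linked segment, since Gdf3 lies 7.12 Mb from Pparg. A chromosome segment carried along with the edited allele may hold a variant that acts on Gdf3 itself. The share of other tested genes near Pparg at an unadjusted p under 0.05 was 2.31% (5 of 216), at percentile 81.3 of 921 windows of as many genes elsewhere (median 1.39%, 95th percentile 2.78%), which decides nothing, because a variant at Gdf3 alone need not move its neighbours. A response to the loss of phosphorylation at Ser273, the biological explanation the design names, and such a linked segment cannot be told apart here, because both travel with the genotype.

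The 35 splits of the 8 libraries into 4 and 4 decide nothing for the count of called genes, since the genotype split called 0 and each split has at least as many; the highest other split called 54. For the other two counts chance could not be excluded: as many rows at an unadjusted p under 0.05 as the 229 of the genotype split were found in 33 of 35 splits, up to 2730, and as many called lists as its 7 in 30 of 35 splits, up to 20. Only 2 of the 35 splits called any gene. The 54 genes came from the split with WT replicate 5 and S273A replicates 2, 4 and 6 on the same side. The other side held WT replicates 1, 2 and 3 and S273A replicate 3. That split was picked for its count. Similarity between libraries did cross genotype. The lowest chi-square per degree of freedom was 5.53, for WT replicate 5 with S273A replicate 6. It was 5.54 for WT replicate 5 with S273A replicate 4 and 5.56 for WT replicate 2 with S273A replicate 3. Within a genotype the lowest values were 7.01 in WT and 7.72 in S273A, though other pairs across genotypes reached 26.1. No formal test of such a structure was run, and its source is not known. The labels name no batch.

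For the called lists, the hypothesis that genotype moved them was set against other splits as well. A camera p as small as the genotype split's was reached in 4 of 35 splits for the mesothelial list (1.26e-11, smallest other 6.27e-15), in 9 of 35 for the red blood cell list (1.89e-06, smallest other 7.32e-42) and in 6 of 35 for the macrophage list (4.35e-05, smallest other 2.09e-08), so chance cannot be excluded for these 3 lists. Nor can it for the other 4 called lists: clock (3 of 35; 0.000793, smallest other 3.46e-08), respiratory chain (14 of 35; 0.000126, smallest other 2.09e-12), cell cycle (18 of 35; 0.000444, smallest other 2.83e-23) and interferon-stimulated genes (18 of 35; 0.00294, smallest other 3.34e-31). Mesothelial scores were -0.10, 0.14, -0.46 and -0.11 in WT replicates 1, 2, 3 and 5 and -0.05, 0.18, 0.41 and -0.01 in S273A replicates 2, 3, 4 and 6.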
